A study of Mus musculus with 6 samples.

How the data were processed

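RNA was measured by sequencing in bone marrow cells sorted for cKit and Sca1 and against lineage markers (the LSK gate, which holds hematopoietic stem and early progenitor cells). The mice were female, wild-type and of the 129S4 strain. Per the labels' protocols, they were 1 month old when they were put for 3 months on rodent chow mixed with SRT3025 at 3.18 g per kg of diet, or on placebo, and 4 months old at collection. SRT3025 is a small molecule developed as an activator of SIRT1, an NAD-dependent deacetylase. Per the labels' protocols, polyadenylated RNA was purified on oligo-dT beads and libraries were made with the Illumina TruSeq RNA kit, which does not mark strand. Each group has 3 libraries, grouped by the drug treatment the labels give, and each column was matched to its library by name.

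The deposited count table holds whole-number read counts per RefSeq transcript accession in each library. Per the submitters' processing notes, the aligner was Bowtie and the genome build mm9. The version of Bowtie, the counter, the transcript annotation, any filter and the tool used for normalization are not given in the sources used here. The table has 14801 transcript rows and 11243 gene symbols, and its smallest row total is 74 counts, so transcripts with very low counts are not represented. Of the symbols, 2305 have 2 or more rows, and the lowest of these rows holds a median 97.1% of the mean of the top row, which fits a read being counted for each transcript it overlaps. A total of 30 rows carried symbols that a spreadsheet had turned into dates, and all 30 were given back their symbol through the accession. The authors also deposited a normalized table, a signal per transcript that equals the deposited count divided by 1 size factor per library, from 0.612 to 0.909. All columns of per-sample values were matched to a library.

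For each gene symbol, the transcript with the highest mean count over the 6 libraries was kept. Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3: filterByExpr with its defaults (minimum count 10), TMM factors, robust dispersion estimates and the two-sided quasi-likelihood test of SRT3025 against placebo over all 6 libraries, with no other term. P-values were adjusted by Benjamini-Hochberg over 11242 genes, with a threshold of 0.05. Levels are TMM-scaled CPM, given as mean ± SD of 3 libraries, and fold changes are on the log2 scale. Reads of near-identical gene copies (histone, ribosomal protein, Ly6, Oas and histocompatibility families) and of overlapping or antisense genes could be split between them or counted for each, so values of such genes are uncertain. H2-Q7 and H2-Q9, for example, had the same value in SRT3025 2 (144.1 CPM) and the same mean in the other libraries (253.2 CPM), so such symbols may hold the same reads. A chi-square of the counts between any pair of libraries was 5.71 to 19.1 per degree of freedom, so no library repeats another within sampling noise.

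Before the data were examined, 35 gene lists were fixed: stem cell identity, lymphoid-primed and myeloid progenitor genes; markers of neutrophils, erythroid cells, megakaryocytes, B cells, T and NK cells, macrophages and dendritic cells, mast cells and basophils, and stroma and endothelium; S phase and G2/M phase genes; p53 targets, sirtuin and NAD genes and FoxO targets; mitochondrial respiration, fatty acid oxidation, cholesterol synthesis, fatty acid synthesis, glycolysis and hypoxia, and autophagy and lysosome genes; inflammatory NF-kB, interferon response, TGF-beta and BMP, Wnt, Notch and Hox genes; immediate-early, heat shock and unfolded protein response, Fanconi and DNA repair, and xenobiotic and antioxidant genes; and ribosomal protein, replication histone and mitochondrially encoded genes. The last of these had 0 tested members, which left 34. The S phase and the Fanconi lists have 1 gene in common. Lists were tested with camera (limma 3.58.1) at the preset inter-gene correlation of 0.01, adjusted over the 34 lists, and again with an estimated correlation, which also leaves fewer degrees of freedom, and with fry. After the results were seen, camera was also run with each list's own estimated correlation as a fixed value, or 0 where the estimate was negative. The edgeR p-values of members were also adjusted over each list alone, with no correction across the 34 lists. A list score is the mean over tested members of log2 CPM (prior count 2) minus the member's mean over the 6 libraries. Scores were compared by a two-sided exact permutation test, for which 3 libraries against 3 allow no p below 0.1.

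Named genes were also chosen by a rule fixed before the data were examined: Sirt1 and the sort markers Kit and Ly6a; up to 10 genes in each direction that pass the test with non-overlapping groups, filled up to 5 with the smallest unadjusted p at a mean of at least 1 CPM where too few pass; and up to 4 passing members of each list, or the 2 members with the smallest unadjusted p where none pass. A few genes that the rule takes are not reported here, in text or plots. Any other gene named in the closing section was chosen after its values were seen. Alternatives planned beforehand were RLE, upper-quartile and no scaling factors, no count filter, a mean of at least 5 CPM, each library left out in turn, the number in the library name as a block, no robust estimation, DESeq2 1.42.0, limma-voom, limma-trend on the normalized signal with pseudocounts of 1 and 0.1, all transcript rows, and summed rows. Alternatives added after the data were seen were the size factors of the normalized table, offsets for transcript GC content and length, and leaving out SRT3025 2 and placebo 3 together.

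The gene test was tested on simulated counts for the same 11242 genes and libraries with 200 genes changed. It recovered 21.5% of genes changed 1.25-fold, 87% at 1.5-fold and 97% at 2-fold, and made 3 calls when no gene was changed. Each fold change had 1 draw, in which genes varied independently, without structure shared by the genes of a library. The draw with no gene changed had 567 genes at an unadjusted p under 0.05 in edgeR, against 354 in the real data. Recovery in the real data may therefore differ. DESeq2 was run on 20 further draws with no gene changed, chosen after the results were seen. In 20 simulated draws in which members vary independently, the S phase list was called in 19 with a log2 shift of 0.1 and in 1 with no shift. With an estimated correlation it was called in 0 draws at a shift of 0.1 and in 18 at 0.2. No genome coordinates are given, because the tables hold none and the reference used for transcript GC content and length is of another build than mm9. GC content and length were found for 11122 of the 11242 genes (98.9%).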

Results

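The transcriptome of sorted LSK cells was profiled in 3 libraries from mice fed SRT3025 and 3 from mice fed placebo. Transcript counts summed to 20331124, 22756915 and 29314817 in SRT3025 1, 2 and 3 and to 28972724, 30134157 and 27231250 in placebo 1, 2 and 3. With 1 transcript kept per gene, libraries held 14828055 to 21924658 counts, and the coefficient of variation between libraries of a group beyond counting noise was 8.43%. SRT3025 2 had the lowest mean correlation with the other libraries, 0.990, and lay at 18.4 on the first principal component, which held 33.8% of the variance, against −9.21 to 0.307 for the other 5. Nothing in the labels says that the libraries came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

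The comparison asked how 3 months of SRT3025 changed gene expression in stem and early progenitor cells of the bone marrow. No single gene differed between the diets past the threshold in edgeR. For 93.5% of genes the 95% interval, taken gene by gene from the spread between these libraries, lay within a 1.5-fold change. Sirt1, which encodes the deacetylase that the compound was developed to activate, was at 50.1 ± 6.04 CPM with SRT3025 and 53.1 ± 3.70 CPM with placebo (SD, n = 3 each), a log2 fold change of −0.082 with a 95% interval of −0.29 to 0.13. Kit, the stem cell factor receptor used in the sort, was at 1156 ± 92.0 CPM against 1120 ± 90.0 CPM. Ly6a, which encodes Sca1, was at 74.1 ± 8.91 CPM against 67.4 ± 8.44 CPM, with log2 fold changes of 0.046 (−0.14 to 0.23) for Kit and 0.14 (−0.10 to 0.37) for Ly6a. Without SRT3025 2 the log2 fold changes of Sirt1 and Kit were 0.010 and −0.018, so the data set no direction for either gene. Ly6a was at 0.039 without SRT3025 2, 0.051 without placebo 2 and 0.23 without placebo 3.

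Of 11242 genes, 0 were higher and 0 lower by the edgeR quasi-likelihood test, and the smallest adjusted p was 0.999. At an unadjusted p under 0.05 there were 354 genes, 123 higher and 231 lower, where chance alone gives 562. The SRT3025 libraries all lay on 1 side of the placebo libraries for 912 genes (8.11%), where chance gives 10%. DESeq2 called 8 genes, all lower, and limma-voom and limma-trend called 0. In 20 simulated draws with no gene changed DESeq2 called 0 to 9 genes, and at least 8 in 2 of them. The 95% interval of the fold change lay within 1.5-fold in either direction for 10508 genes (93.5%) and within 2-fold for 11129 (99%).

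**Figure D1:**
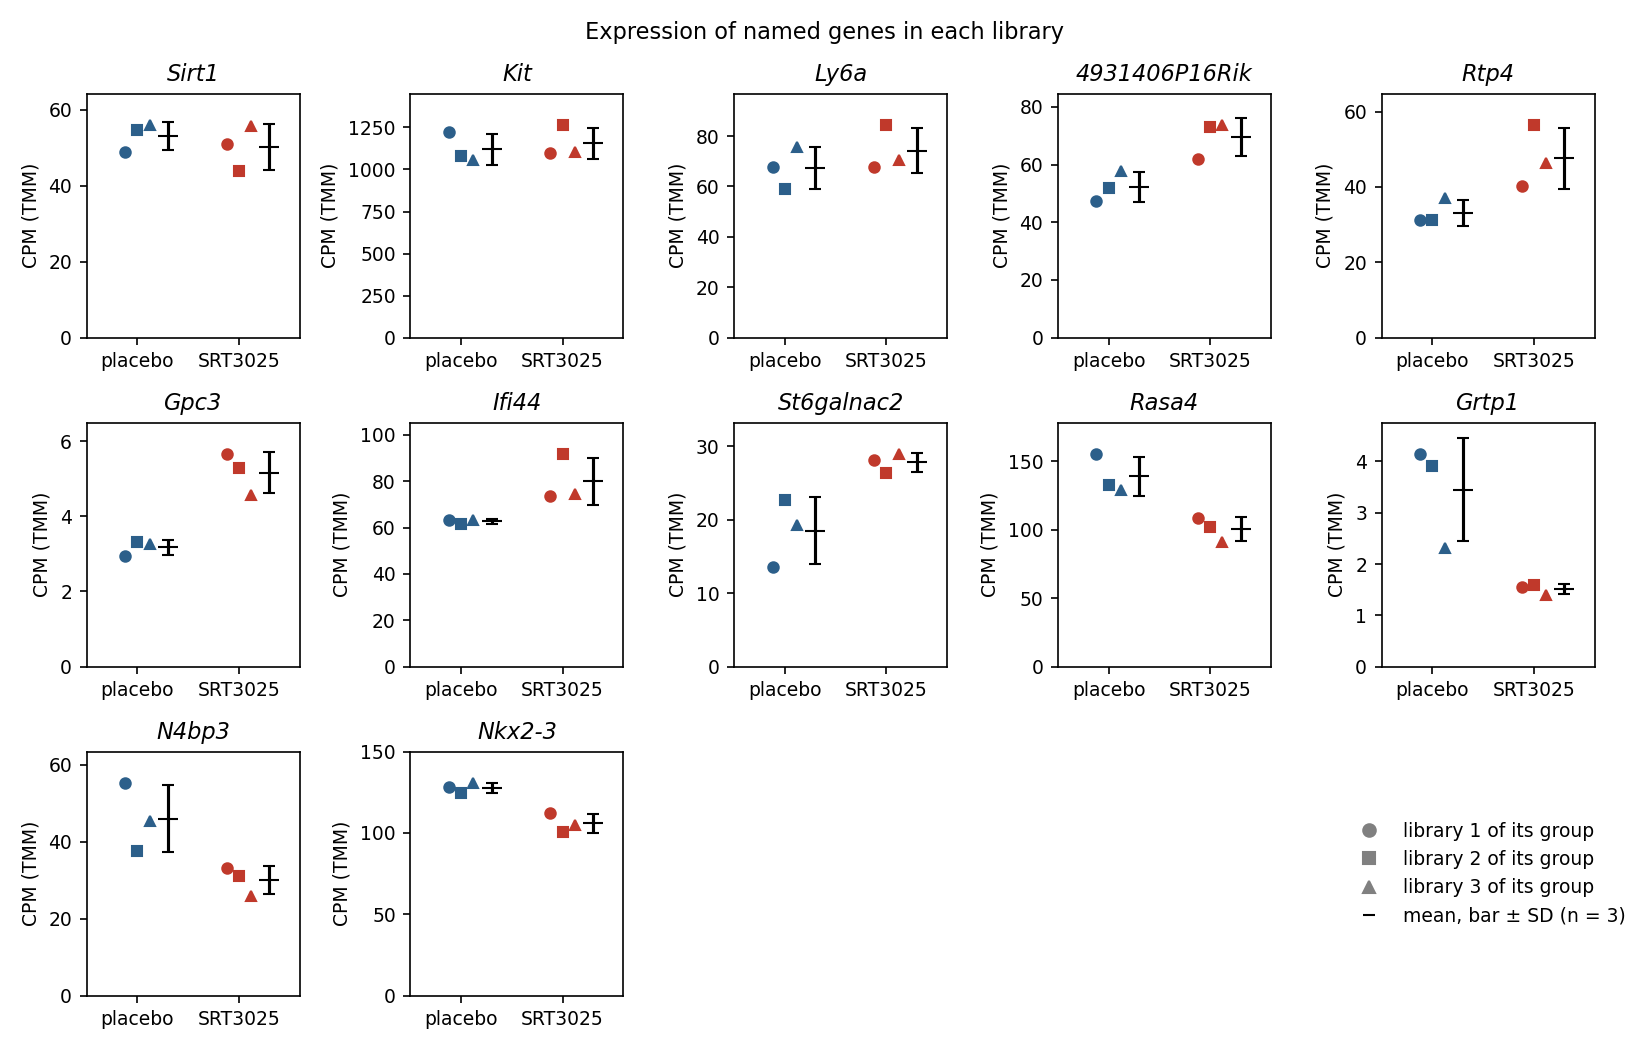
Expression in TMM-scaled CPM of Sirt1, the sort markers Kit and Ly6a, and 5 higher and 4 lower genes among those with the smallest unadjusted p, with each library as a point and the mean ± SD of 3 libraries beside it. Sirt1, Kit and Ly6a overlap between the groups, and the other 9 genes, picked for small p-values, do not overlap but miss the adjusted threshold in edgeR.

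The 5 genes with the smallest unadjusted p on the higher side included Rtp4 and Ifi44, both induced by interferon. Rtp4 was at 47.6 ± 8.16 CPM with SRT3025 and 33.2 ± 3.42 CPM with placebo, a log2 fold change of 0.52 (SE 0.12), and Ifi44 at 79.9 ± 10.2 against 62.7 ± 1.02 CPM, 0.35 (SE 0.089). The others were Gpc3, a cell-surface proteoglycan, at 5.16 ± 0.554 against 3.17 ± 0.197 CPM, St6galnac2, a sialyltransferase, at 27.8 ± 1.29 against 18.5 ± 4.61 CPM, and 4931406P16Rik at 69.5 ± 6.66 against 52.2 ± 5.22 CPM. On the lower side, Rasa4, a Ras GTPase activator, was at 100.5 ± 8.90 against 139 ± 14.1 CPM (log2 fold change −0.47, SE 0.088). Grtp1 was at 1.51 ± 0.105 against 3.45 ± 0.999 CPM, N4bp3 at 30.1 ± 3.70 against 46.0 ± 8.80 CPM, and Nkx2-3, a homeodomain transcription factor, at 106.1 ± 5.85 against 127.8 ± 3.04 CPM. The adjusted p of each of these 9 genes in edgeR was 0.999. The genes that DESeq2 called included Rasa4 (adjusted p = 0.0121) and N4bp3 (0.0299), and 5 further genes outside the rule for named genes: Ern1, Fxyd1, Pgr, Cecr6 and Creb5 (adjusted p from 0.0129 to 0.0357).

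**Figure D2:**
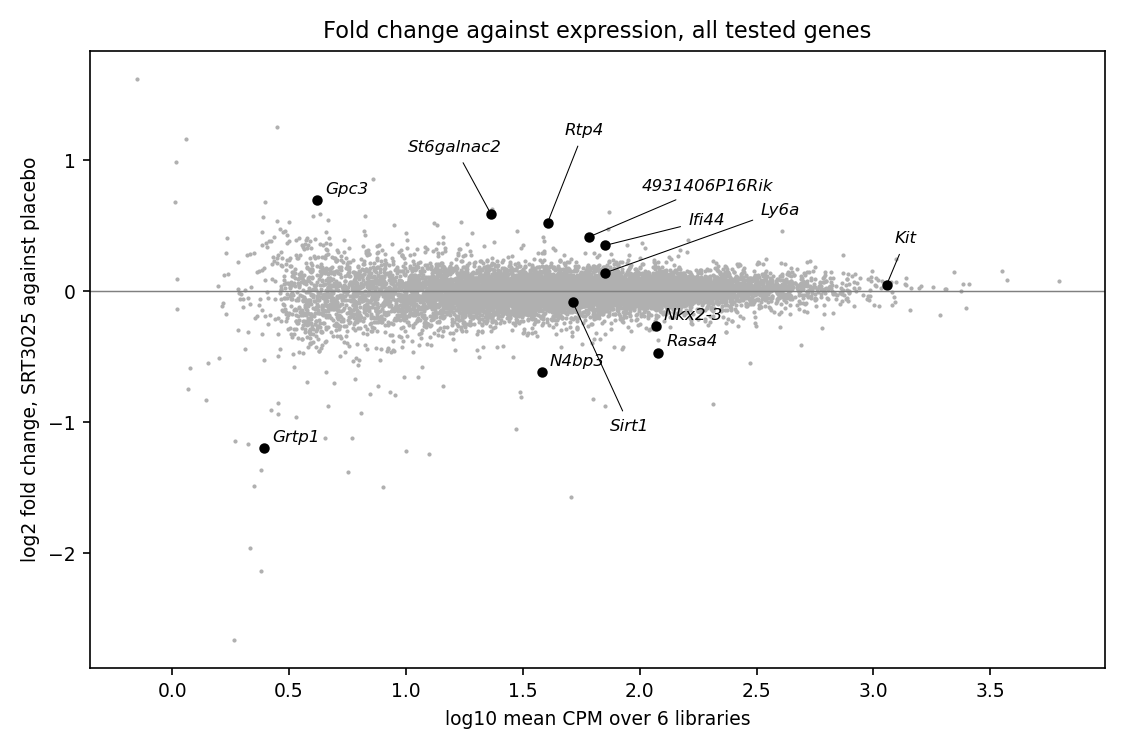
Log2 fold change of SRT3025 against placebo for each of 11242 tested genes against log10 of the mean CPM over the 6 libraries, with the named genes in black. The points scatter around 0, with a median of −0.000572 over all genes, and spread more widely at low expression.

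Groups of genes moved by small amounts in camera at its preset correlation, which called 9 of the 34 lists, 3 higher and 6 lower. None of the 9 was called with an estimated correlation between members or by fry, where 0 of 34 lists passed in each and 2 and 3 lists had an unadjusted p under 0.05. At the preset correlation 11 had one. Across genes, which are not independent replicates, fold changes also went with transcript GC content (Spearman's rho −0.302) and length (rho 0.192). The GC trend was uneven between libraries of a group: the rho of a library's deviations with GC was −0.448 in SRT3025 3 and 0.332 in placebo 1, against −0.0500 and 0.130 in SRT3025 1 and 2 and −0.0323 and 0.0982 in placebo 2 and 3. With length it was −0.102, 0.231 and 0.0334 in SRT3025 1 to 3 and −0.144, 0.0637 and −0.189 in placebo 1 to 3. After offsets for both 7 of the 9 lists kept their calls and 3 others were called, while with the offsets and an estimated correlation no list was (smallest adjusted p = 0.490). Calls of other lists under changed settings, given below, are all at the preset correlation. The S phase list, genes of the DNA replication machinery, was called higher: 32 of its 33 members had a positive fold change, with a median of 0.17 (adjusted p = 1.51e-15, and adjusted p = 0.446 with an estimated correlation). Dtl was at 175.9 ± 16.5 CPM with SRT3025 and 143.3 ± 18.4 with placebo, and Mcm4, a subunit of the replicative helicase, at 279.7 ± 20.6 against 242.7 ± 20.4. No S phase gene passed alone. The difference in mean list score was 0.158 on the log2 scale (exact permutation p = 0.2), and without placebo 1 it was 0.0908. The G2/M list was not called, with 8 of its 33 members positive, 25 negative and a median of −0.056 (adjusted p = 0.187). It was called lower after GC and length offsets (adjusted p = 0.0285, and 0.964 with an estimated correlation), without SRT3025 1 (4.53e-07) and without placebo 1 (7.46e-08). Its score difference of −0.0397 turned positive without placebo 2 (0.0474), SRT3025 3 (0.0246) or SRT3025 2 (0.00292), so the list has no settled direction. The Fanconi and DNA repair list, which has 1 gene in common with the S phase list, was called higher with 17 of 26 members positive and a median of 0.095 (adjusted p = 0.00304, and adjusted p = 0.653 with an estimated correlation). Its members Brca1 and Atm, both of the DNA damage response, had log2 fold changes of 0.28 and 0.16. The call ended without SRT3025 1 (adjusted p = 0.135) and without placebo 1 (0.358), where the score difference of 0.0770 became 0.0462 and 0.0202, and without placebo 3 the difference was 0.118.

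The interferon response list was called higher, with 31 of 39 members positive and a median of 0.15 (adjusted p = 1.43e-10, and adjusted p = 0.444 with an estimated correlation). Rtp4 and Ifi44 passed when adjusted over the list alone, both at an adjusted p of 0.0458, against 0 members over all genes tested. All 3 SRT3025 libraries scored above all 3 placebo libraries, 0.0762 ± 0.140 against −0.0762 ± 0.0295 (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). The margin was narrow: SRT3025 1 scored −0.0327 and SRT3025 3 scored 0.0277, against −0.0437 in placebo 3. Scores of the groups did not overlap for 4 of the 34 lists, where chance gives 10% of lists, so such a separation is weak evidence. SRT3025 2, which stood apart on the first principal component, had the highest score, 0.234. Without it the difference was 0.0737 instead of 0.152, and the list was still called at the preset correlation (adjusted p = 0.00173) but not with its own correlation estimated without that library as a fixed value (0.226). In the same library the macrophage and dendritic cell markers had their lowest score, −0.1998.

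Among sirtuin and NAD genes no member passed alone, and the list was called lower at the preset correlation only. FoxO targets, also fixed as a list for the compound's pathway, were not called by camera (14 positive, 10 negative, median 0.0081, adjusted p = 0.733). Of the sirtuin and NAD list, 12 of 17 members were negative and 5 positive, with a median of −0.070 (adjusted p = 0.0150, and adjusted p = 0.444 with an estimated correlation). Sirt7, a nuclear sirtuin, was at 64.5 ± 2.77 CPM with SRT3025 and 75.6 ± 2.02 CPM with placebo, and Sirt4, a mitochondrial one, at 25.9 ± 2.18 against 29.9 ± 1.45 CPM. Their groups did not overlap, but neither gene passed the test. The list's scores did not overlap either (difference −0.103, exact permutation p = 0.1), and its call ended without SRT3025 3 (adjusted p = 0.0598) and without placebo 3 (0.168). The score difference was −0.106 without SRT3025 3, so it did not shrink there, and −0.0796 without placebo 3. The p53 target list was called lower, with 18 of 25 members negative and a median of −0.046 (adjusted p = 0.0182, and adjusted p = 0.444 with an estimated correlation). Its members Ddit4, an inhibitor of mTORC1, and Bbc3, which encodes the pro-apoptotic protein Puma, had log2 fold changes of −0.43 and −0.28 (−0.16 for Bbc3 after GC and length offsets). The p53 scores differed by −0.118 with no overlap (exact permutation p = 0.1), and the call ended without SRT3025 1 (adjusted p = 0.0576), SRT3025 2 (0.123) or placebo 2 (0.0749). In these 3 fits the p53 score difference was −0.118, −0.101 and −0.103.

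The list of Hox cluster transcription factors and their partners was called lower, with 13 of 15 members negative, 2 positive and a median of −0.12 (adjusted p = 0.000609, and adjusted p = 0.444 with an estimated correlation). Hoxa9, which promotes self-renewal of hematopoietic progenitors, was at 97.6 ± 2.70 CPM with SRT3025 and 111.5 ± 2.37 CPM with placebo (log2 fold change −0.19), and Hoxa3 at 28.4 ± 2.65 against 35.3 ± 2.03 CPM (−0.31). No Hox list member passed alone or when adjusted over the list alone. The Hox scores overlapped (difference −0.119, exact permutation p = 0.2), and the call held with any 1 library left out. The Notch list was called lower with 7 of 10 members negative and a median of −0.075 (adjusted p = 0.0475, and adjusted p = 0.444 with an estimated correlation). Nrarp, a target and feedback inhibitor of Notch signalling, had a log2 fold change of −0.31 and passed when adjusted over the list alone (adjusted p = 0.0287), and Dtx3 had −0.23. The Notch call ended without SRT3025 1 (adjusted p = 0.127), SRT3025 3 (0.150) or placebo 3 (0.421, with a score difference of −0.0197 instead of −0.0731), after GC and length offsets (0.0800) and with scaling by total counts (0.0555). The immediate-early list was called lower with 16 of 20 members negative and a median of −0.11 (adjusted p = 0.0442, and adjusted p = 0.750 with an estimated correlation). Its members Socs3 and Jund had log2 fold changes of −0.43 (−0.21 without placebo 3) and −0.24 (−0.11 after offsets and also without placebo 1). The call ended without placebo 3, which scored 0.398 on this list and 0.841 on the neutrophil list. Without that library the adjusted p in camera was 0.893 and the score difference 0.00727 instead of −0.154. The call also ended without SRT3025 1 (0.0906) or SRT3025 2 (0.355, difference −0.0993), after GC and length offsets (0.219) and with scaling by total counts (0.0555). Without placebo 2 the difference was −0.251.

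**Figure D3:**
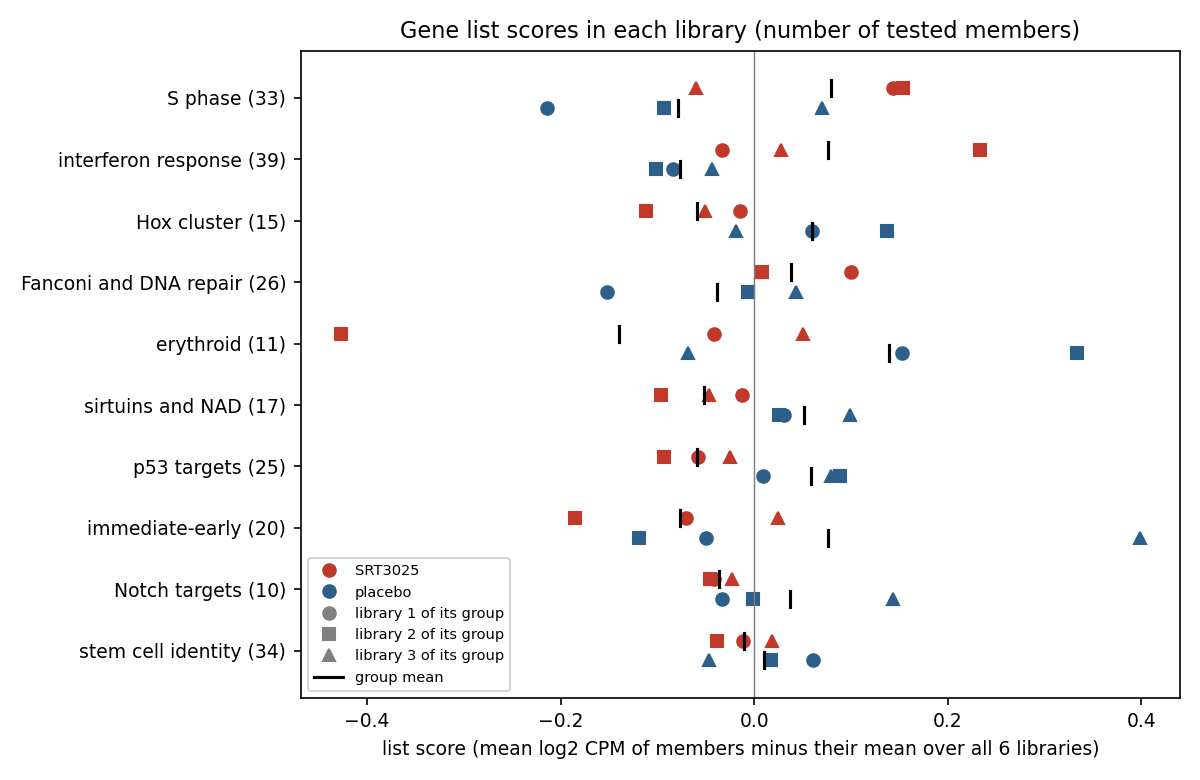
Score of each library (mean log2 CPM of a list's tested members minus their mean over the 6 libraries) for the 9 called lists and the stem cell identity list, with red points for SRT3025, blue for placebo and a bar at each group mean. The groups do not overlap for the interferon, sirtuin and p53 lists, while SRT3025 2 stands apart on the interferon (0.234) and erythroid (−0.427) lists and placebo 3 on the immediate-early list (0.398).

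Stem cell identity genes were not called as a group: 15 of 34 members were positive and 19 negative, with a median of −0.013 (adjusted p = 0.683). Hoxa9 and Slamf1, which encodes the stem cell marker CD150 (log2 fold change 0.28), had the smallest unadjusted p-values in it. Lymphoid-primed progenitor genes had a median of −0.071 (adjusted p = 0.2005), with Il12rb1 at −0.30 (−0.14 without SRT3025 3) and Ccr9 at −0.41, and were called lower without SRT3025 2 (adjusted p = 0.0103) and without placebo 1 (0.0345), while the score difference of −0.0944 became 0.0152 without SRT3025 3. Myeloid progenitor genes had a positive median of 0.071, while their mean of −0.043 and the test were negative (adjusted p = 0.898). Within it Csf2ra had −0.21 (−0.11 after offsets) and Ctsg, the granule protease cathepsin G, 0.37.

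Of the markers of other cell types, the erythroid list was called lower, with 8 of 11 members negative and a median of −0.082 (adjusted p = 0.00315, and adjusted p = 0.653 with an estimated correlation). Ermap was at 1.33 ± 0.461 CPM with SRT3025 and 3.45 ± 1.26 CPM with placebo, and Car1, carbonic anhydrase 1, at 3.67 ± 1.54 against 8.06 ± 2.72 CPM. Both passed when adjusted over the list alone, at 0.0215 and 0.0353. The erythroid call ended without SRT3025 2 (adjusted p = 0.355) and without placebo 2 (0.0986), where the score difference of −0.279 became −0.135 and −0.182, and with genes under a mean of 5 CPM left out (0.0990). Macrophage and dendritic cell markers missed the threshold (median −0.20, adjusted p = 0.0514), with scores that did not overlap (difference −0.166, exact permutation p = 0.1). They were called lower after GC and length offsets (adjusted p = 0.0487, and 0.490 with an estimated correlation), with DESeq2 size factors (0.0436), upper-quartile factors (0.0455), the replicate block (0.00733) or no robust estimation (0.0269), and without placebo 1 (0.0432). Without SRT3025 2 the difference was −0.108. Cd74, the invariant chain of class II histocompatibility molecules, and Itgax had log2 fold changes of −0.25 (−0.11 without SRT3025 2) and −0.23. The median was 0.57 for the mast cell and basophil list (adjusted p = 0.101), where Cpa3 had 0.35 and Mcpt8 0.57 (0.33 without SRT3025 1), and which was called higher without SRT3025 2 (0.0103) and without placebo 2 (0.0396). The score difference of this list, 0.319, became 0.122 without placebo 1. The median was −0.69 for the neutrophil list (0.2005), where Itgam had −0.23 and S100a8 −0.85 (0.031 without SRT3025 2 and placebo 3). The neutrophil score difference of −0.323 became 0.0167 without placebo 3, −0.159 without SRT3025 3, −0.542 without SRT3025 1 and −0.651 without placebo 2, where the list was called lower (adjusted p = 0.000228). The median was −0.047 for the megakaryocyte list (0.328), where Thbs1 had −1.57 with an SD of 54.7 CPM in placebo (−0.81 without placebo 1) and Selp −0.24 (−0.030 without SRT3025 2), and which was called lower without SRT3025 3 (0.0166) and without placebo 3 (0.0161), while its score difference of −0.151 became −0.0265 without SRT3025 2 and −0.0440 without placebo 1. The B cell list had 3 tested members and a median of −0.011 (0.733), with Igj at −1.24 (−0.73 without SRT3025 3) and Cd24a at −0.011, which was positive without SRT3025 3 (0.078). In the T and NK cell list the median of −0.067 and the mean of 0.027 differed in sign (0.733). Thy1 had 0.44 there and passed in edgeR when adjusted over the 6 tested members alone (adjusted p = 0.0223, against 0.999 over all genes), and Lat had −0.097. The stroma and endothelium list had a median of −0.023, with the test on the positive side (0.967), and held Bgn at −0.33 (−0.14 without placebo 1) and Pdgfrb at 0.15.

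Metabolic lists were not called with all 6 libraries and no offsets. Mitochondrial respiration genes had a median of 0.019 (adjusted p = 0.325), with Cox5b at 0.19 and Idh3a at 0.10. They were called higher after GC and length offsets (adjusted p = 0.0285, and 0.941 with an estimated correlation), without SRT3025 3 (0.0357) and without placebo 3 (0.0126), while the score difference of 0.0158 turned negative without SRT3025 1 (−0.00266) and without placebo 2 (−0.00522). Fatty acid oxidation genes had a median of 0.0049 (0.753), with Cpt1a, the carnitine palmitoyltransferase of liver type, at 0.24 (0.10 without SRT3025 3 and 0.38 without SRT3025 2) and Acadl at 0.13. Cholesterol synthesis genes had −0.033 (0.733), with Stard4 at 0.10 and Sc4mol at −0.32 (−0.068 without placebo 3), and were called lower without SRT3025 2 (0.0241) and without placebo 2 (0.000548), while the score difference of −0.0524 became 0.0577 without SRT3025 3 and 0.0417 without placebo 3. The fatty acid synthesis list had a median of −0.016 and a mean of 0.018, with the test on the positive side (0.683), Acaca at 0.29 (0.11 without SRT3025 2) and Acacb at 0.16 (0.070 without placebo 3). In the glycolysis and hypoxia list the median of 0.010 was positive and the mean of −0.014 and the test were negative (0.873). Vegfa, the vascular growth factor, had −0.50 there and passed when adjusted over the list alone (adjusted p = 0.0478), and Hk2 had −0.18 (−0.0018 without placebo 3). Autophagy and lysosome genes had a median of −0.023 (0.733), with Atg16l1 at −0.16. FoxO targets had a median of 0.0081 (0.733), with Bcl6 at −0.38 (−0.16 without placebo 1) and Cited2 at 0.37 (0.095 without SRT3025 3).

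Among signalling and stress lists, the TGF-beta and BMP list had a median of −0.0057 (adjusted p = 0.792), while Skil, a repressor of Smad signalling, at −0.30 and Tgfbr3, the type III receptor, at 0.33 both passed when adjusted over the list alone (adjusted p = 0.0493 each). The list was called lower without both SRT3025 2 and placebo 3 (0.0476). The Wnt list had a median of −0.014 and a mean of −0.017, with the test on the positive side (0.877), Fzd7 at 0.11 and Cd44 at 0.082. The inflammatory NF-kB list had a median of −0.015 (0.808), with Rel at 0.19 and Icam1 at −0.10. Heat shock and unfolded protein response genes had −0.024 (0.648), with Dnajb9 at −0.21 and Creld2 at −0.17, and were called lower without SRT3025 3 (0.00926), while the score difference of −0.0249 became 0.0483 without SRT3025 1. Xenobiotic and antioxidant genes had 0.0046 (0.683), with Nqo1 at 0.19 and Gsr at 0.10. Ribosomal protein genes had a median of −0.014 over 51 members (0.898), with Rps10 at −0.13 and Rps4x at 0.099, and were called higher without SRT3025 2 (0.0103), where the score difference was 0.0374 instead of −0.0169. The 4 tested replication histone genes had a median of −0.064 and a mean of 0.034, with the test on the positive side (0.792), Hist1h2bc at 0.40 and Hist2h2be at −0.14 (0.022 without placebo 3). Of the list members named here with no value of their own for a left-out library, 1 left-out library moved the log2 fold change by over 1.5 times for Acadl, Atg16l1, Cd44, Cox5b, Ctsg, Dnajb9, Fzd7, Hist1h2bc, Icam1, Lat, Nqo1, Rps10 and Rps4x.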

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

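Chosen only after the results were seen were the fits with the size factors of the normalized table, with GC and length offsets, and without both SRT3025 2 and placebo 3. The number of genes past the threshold in edgeR or limma was 0 in each of the 21 settings other than DESeq2, which called 8. Leaving out libraries gave 0 genes each time, with 162 to 703 at an unadjusted p under 0.05. Camera called 9 lists, and 7 to 10 under other scalings, filters, dispersion settings and offsets. It called 6 with SRT3025 1 left out (5 of the 9 among them) and up to 11 with other libraries left out, so a range of 6 to 11. Camera with an estimated correlation called 0 lists and fry 0. Part of the former follows from its construction, since it leaves few degrees of freedom and in simulated draws with independent members called a list shifted by 0.1 in 0 of 20; for fry the cause was not tested. For the 9 lists, 120 of 162 values kept direction and side of the threshold, 41 lost the call and 1 reversed. The reversed value was the immediate-early list without both libraries (adjusted p = 0.424, upward), and its range over left-out libraries was 2.19e-05 to 0.893. Adjusted p-values over all alternatives ran from 2.43e-25 to 0.941 for S phase, 4.07e-15 to 0.739 for interferon, 0.000195 to 0.444 for Hox, 9.75e-06 to 0.941 for Fanconi, 1.91e-05 to 0.941 for erythroid, 0.00453 to 0.444 for sirtuin, 0.00130 to 0.444 for p53, 2.19e-05 to 0.941 for immediate-early and 0.00771 to 0.444 for Notch. For the 78 named genes, 1542 of 1553 values kept direction and side. Rasa4 (−0.47) and N4bp3 (−0.61) were among those that passed in DESeq2. Over left-out libraries the log2 fold change ran through 0 for Sirt1 (−0.17 to 0.0448), Kit (−0.0630 to 0.11), Cd24a (−0.0712 to 0.0784), Hist2h2be (−0.22 to 0.0216) and S100a8 (−1.26 to 0.0306), and the cause was not tested. A single left-out library moved the value by over 1.5 times or turned it for 38 of the 78, and GC and length offsets did for 9 (Bbc3, Cd44, Csf2ra, Icam1, Jund, Kit, Lat, Nkx2-3 and Rps10), so these values are not stable. With the replicate block, 0 genes and 9 lists were called, 8 of them among the 9, with Notch lost (adjusted p = 0.0706). The deviations of same-numbered libraries correlated at 0.0591, −0.131 and −0.00120, and no SRT3025 library correlated best with the placebo library of its number. No large shared effect of the number was therefore seen, but so few pairs cannot exclude a smaller one. At 14828055 to 21924658 gene counts per library, the smallest simulated changes were recovered in 21.5% of genes and changes of 1.5-fold in 87%. The simulated genes varied independently, so these shares may not hold for the real libraries.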

Other observations

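The tests of GC content and length, of shared variation, of single libraries and of other cell types were chosen only after the results were seen, as were the genes named here for standing apart in 1 library. SRT3025 2 differed from the other 5 libraries in genes of several kinds. Fn1, which encodes fibronectin, was at 7.62 CPM there and at 1.24 to 2.29 CPM in the others. The antiviral genes Oas2 and Oas3 were at 40.4 and 72.8 CPM, against at most 24.3 and 42.03 CPM elsewhere. Hmga2 and Igf2bp2, which belong to the fetal stem cell program, were at 29.8 and 16.1 CPM against at most 18.6 and 11.4 CPM. Aldh1a1, a retinaldehyde dehydrogenase of stem cells, was at 15.2 CPM against at least 40.1 CPM, Sdpr at 2.46 against at least 7.04 CPM, and H2-Eb1 at 53.2 against at least 109.2 CPM. In that library 3 genes lay over 2-fold above all other libraries and 11 lay over 2-fold below. The 3 were Fn1 and, at low levels, the collagen gene Col1a1 (3.44 CPM against a mean of 0.692 in the others) and the mast cell gene Tpsb2 (3.13 against 0.625). The stroma and endothelium list scored 0.271 there and 0.313 in placebo 1, against −0.205 to −0.0857 in the other libraries.

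The other libraries had marks of their own. In SRT3025 3, Itgb3, the platelet integrin beta 3, was at 166.6 CPM against 44.6 to 61.1 CPM in the other 5. Rag1 and Rag2, the recombinases of lymphoid progenitors, were also lowest there, at 3.02 and 2.65 CPM. In placebo 1, Thbs1 was at 139.6 CPM against at most 48.6 CPM, Cxcl12 at 11.2 against at most 5.72 CPM, and Creb5, one of the 8 genes that DESeq2 called, at 7.51 against at most 2.32 CPM. Of the other genes that DESeq2 called, Cecr6, Ern1, Pgr, Rasa4 and N4bp3 were also highest in placebo 1. Ern1, for example, was at 437.2 CPM there against 320.6 and 294.7 CPM in placebo 2 and 3. The remaining calls were not highest there, such as Fxyd1, at 16.8 CPM in placebo 2 and 15.6 CPM in placebo 1. Genes over 2-fold above all other libraries numbered 7 in placebo 1, 8 in placebo 3, 2 in SRT3025 3 and 0 in SRT3025 1 and in placebo 2.

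The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 0 genes in edgeR and the highest of the others 0, so 10 of 10 were as large, which a count of 0 fixes beforehand and which says nothing. In DESeq2 the real split gave 8 genes and the highest of the others 30, with 4 of 10 as large, and in camera it gave 9 lists against a highest other of 10, with 6 of 10 as large. The split with 30 had 0 in edgeR. A count of 30, from a split that mixes the diets, was above the at most 9 calls that DESeq2 made in 20 simulated draws with no gene changed. The draws varied each gene independently, with dispersions fitted under the real grouping, and 30 is the highest of several splits. They therefore cannot tell structure shared by the genes of a library from single genes that stood out in 1 library. For the list calls as a set, a trend with transcript GC content and length, strongest in SRT3025 3 and placebo 1 for GC, was argued against as the whole cause. After offsets for both, 7 of the 9 lists stayed called. The medians of the immediate-early and Notch lists, which lost their calls, shrank from −0.105 to −0.0394 and from −0.0755 to −0.0468. Among the lists that stayed called, the median shrank from 0.0947 to 0.0632 for Fanconi, −0.0823 to −0.0571 for erythroid, −0.122 to −0.0948 for Hox and −0.0700 to −0.0600 for sirtuin. It changed little for S phase (0.172 to 0.176), interferon (0.149 to 0.145) and p53 (−0.0457 to −0.0463). Members varying together between libraries of 1 group may account for 6 of the calls: the estimated correlation of those lists was 0.169 to 0.638, above the preset 0.01 within its 95% bounds, and with it as a fixed value their unadjusted p rose to 0.0143 to 0.195 and 0 of the 6 were called. The sirtuin, p53 and Notch lists also lost their calls then (adjusted p = 0.0513, 0.0513 and 0.0922), although their unadjusted p fell, from 0.00264 to 0.00223, 0.00375 to 0.00302 and 0.0126 to 0.00917, so they were lost through the adjustment over lists. The Notch estimate was negative, so its fixed value was 0. For these 3 lists shared variation stays open, as the 95% bounds of all 3 estimates (0.00759, 0.00767 and −0.0110) hold the preset value. A response to the diet also stays open.

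The higher interferon list is a pattern that may be followed up. Its unadjusted p was 8.39e-12 in the real split and 8.87e-09 to 0.219 in the other 9, and that of the S phase list 4.44e-17 and 2.56e-36 to 0.966; each of the 9 keeps 2 SRT3025 libraries together, so they are no comparison free of diet. SRT3025 2 alone as its source stays open: without that library the list was called at the preset correlation (adjusted p = 0.00173) but not with its own correlation as a fixed value (0.226), and the score difference was 0.0737 instead of 0.152. More macrophages or dendritic cells in SRT3025 2 were not excluded, although their 11 tested markers scored −0.1998 there. Cd74 was at 120.5 CPM in that library against at least 164.2 CPM in the others. The class II markers H2-Aa, H2-Ab1 and H2-Eb1 were also low, at 65.21, 61.15 and 53.22 CPM against means of 126.3, 106.3 and 122 CPM. As class II genes that moved together weigh on the score, it cannot tell fewer cells from lower class II expression. The lineage sort would remove most macrophages and dendritic cells. Shared variation of interferon genes between libraries that is unrelated to the diet stays open, as does an effect of SRT3025 itself, which remains a hypothesis.

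Placebo 3 stood out for immediate-early and neutrophil genes. Egr1 was at 225.9 CPM there against at most 81.3 CPM in the other libraries, Fos at 13.1 against at most 3.36, and the p53 target Cdkn1a at 64.3 against at most 27.9. The beta hemoglobin gene Beta-s was also high there, at 6.16 CPM against a mean of 1.30 CPM in the others, while the erythroid list scored −0.0683 in placebo 3. The lower immediate-early list with SRT3025 may come from this library, since without it the adjusted p was 0.893. RNA from mature neutrophils, which the sort should remove, may be part of it: 4 of the 7 tested neutrophil genes were highest there (all 7 were detected in each library), with S100a9 at 15.8 CPM against at most 6.79 and Ngp at 12.4 against at most 6.05, but Lyz2 at 181 CPM was within the range of the others and Cxcr2, at 4.16 CPM, was the lowest of the 6. These values leave neutrophil RNA open, and whether handling of that sample or its animal differed was not tested.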
